A study of Xenopus laevis with 5 samples.

How the data were processed

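RNA was measured in 5 samples of Xenopus laevis animal cap explants, the presumptive ectoderm of the blastula and early gastrula, which forms epidermis in culture. Per the labels, embryos were injected at the 2-cell stage with synthetic mRNA for ICD (3 samples) or HMM (2 samples), raised in 0.1X MMR, a frog saline, and cut at stage 9 to 10. The explants were kept in Danilchik's medium with 0.1% BSA until the equivalent of stage 22. Total RNA was extracted with proteinase K, and biotin-labelled cRNA was hybridised to Affymetrix expression arrays with 1 colour. The series title names Notch signalling in the epidermis. The labels do not spell out ICD and HMM. In this field ICD commonly stands for the intracellular domain of Notch, which activates the pathway's targets, and HMM for a truncated human Mastermind, which blocks them. That reading is background here and enters no test. No uninjected explants were analysed here, so which of the 2 groups moved cannot be told for any gene. Below, rose and fell mean higher and lower in ICD than in HMM.

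The authors deposited linear signal intensity values, 1 per probe set and array. The submitters' processing notes name MAS5, with no version given. MAS5 summarises the perfect-match and mismatch probes of a probe set into a signal and scales each array to a common trimmed mean. The 2% trimmed mean was close to 200.03 on every array, so the deposited intensities were used with no further scaling. Detection calls were not used here, and the authors' other settings are not given in the sources used here. A MAS5 signal of a dim probe set carries a large relative error, because mismatch signal is subtracted. Scaling to a common mean removes any difference in total RNA between the samples.

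The table held 15611 probe sets. The 120 control probe sets were left out, which left 15491. A table of the platform's annotation gave 1 gene symbol to 9304 of them, several to 195 and none to 5992. Of the probe sets with several symbols, 160 carried both homeologs (.L and .S) of a gene. Gene IDs of 9227 of the 1-symbol probe sets were found in a RefSeq gene table of the assembly Xenopus_laevis_v10.1, which updated 2 symbols. No genome sequence was used and no coordinates are given. Probe sets with several symbols were not named and did not enter the gene lists, and probe sets without a symbol were tested but stay unnamed.

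Values were tested as log2(value + 5.9), the pseudocount being the 10th percentile of all values. A probe set was kept where it lay above 42.6, the 40th percentile, on at least 2 arrays, which left 9981 probe sets. Differences are ICD minus HMM on this scale, so they understate the change of genes near the pseudocount. The model was limma's lmFit and eBayes with a variance trend (limma 3.58.1, R 4.3.3), fitted to all 5 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. Every adjusted p of a gene comes from limma.

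Before the data were examined, 17 gene lists were written from textbook knowledge of the larval skin, together with the rule for the genes to name and the alternatives. Matching by symbol or synonym gave 693 probe sets with 1 symbol, 37 of them by synonym. A further 19 matches to a different gene were removed by hand before any difference was looked at. For each gene the kept probe set with the highest mean stood for it, and homeologs stayed apart. Lists with at least 5 measured genes (15 of 17) were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the 15 lists. Camera asks whether a list differs from the other genes. It was repeated with an estimated correlation. In that form the test has only the 3 residual degrees of freedom of the fit, so few lists could pass whatever their correlation. The method fry, which asks whether a list's genes move one way on balance, was run as well. The named genes were the 12 largest called differences in each direction with non-overlapping groups and an informative symbol, up to 4 members with the smallest p in each list, and a fixed set of regulators and markers.

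The alternatives were quantile normalization, median centring, no pseudocount and 4 times the pseudocount, no filter and a filter at the 60th percentile (110.7), eBayes without trend and with robust estimation, each array left out in turn, the replicate number as a block, 2 other thresholds, and, for the lists, other ways of taking probe sets together. Including homeolog pairs and counting list members with each array left out were added after the data had been seen.

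The fit was tested on simulated data with the real means and the spreads estimated by the fit, for the comparison of ICD with HMM. Noise was drawn independently for each probe set and array. The simulation thus lacks differences shared by arrays or genes, and its rates may be too favourable. Of the 200 probe sets given a known change singly among 9792 fitted, the test called 19.4% of those changed 2-fold, 85.1% of those changed 4-fold and 98.5% of those changed 8-fold. A further 40 were shifted together as a list. Of the 153 calls, 14 fell on unchanged probe sets. The number of arrays limits the precision: the fit had 3 residual degrees of freedom, and the labels do not say whether the replicates came from separate clutches. The p-values measure the spread between these samples, which may be technical in part.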

Results

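Gene expression was measured in epidermal explants of Xenopus laevis that developed under 1 of 2 injected mRNAs, ICD (3 arrays) or HMM (2 arrays), and were harvested at the equivalent of stage 22. Median signal per array lay between 62.1 and 72.7, and the number of probe sets above the filter value ranged from 8908 to 9463. Arrays of a group correlated with each other at 0.948 to 0.971 across probe sets, and arrays of different groups at 0.878 to 0.936. These correlations are across genes, which are not independent replicates. The ICD and HMM arrays lay on opposite sides of the first principal component, which held 59.2% of the variance. On the second component (27.2%), ICD replicate 1 and HMM replicate 1 lay at 32.8 and 33.5, while ICD replicates 2 and 3 and HMM replicate 2 lay at -30.7, -26.4 and -9.17. ICD replicate 3 stood apart in its spike-in controls: the median of its 24 poly-A control probe sets was 2.95, against 318.2 to 355.5 on the other 4 arrays.

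The comparison of ICD with HMM asks which epidermal genes depend on Notch activity, as the title of the series frames it. As a check of the injected pathway, the probe set for notch1.S, the Notch receptor gene, read 232 ± 55.9 in ICD (SD, n = 3) and 113 ± 35.4 in HMM (SD, n = 2), a difference of 1.00 ± 0.33 (SE) on the log2 scale that did not pass the threshold (limma adjusted p = 0.148). Whether this probe set lies within the injected RNA is not known here, so it does not check the labels.

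Explants injected with ICD had far lower transcript levels of ionocyte and ciliary genes than explants injected with HMM. Fewer genes were higher, among them the keratin gene krt19, the secretory gene agr2, the Notch ligand gene jag1 and the collagen gene col18a1. Of 9981 probe sets, 504 passed the threshold, 155 higher in ICD and 349 lower. By gene, these were 90 higher and 186 lower, and 192 of the called probe sets had no symbol. The falls were also larger: 84 called probe sets were at least 8-fold lower in ICD and 1 was at least 8-fold higher. In all, 1959 probe sets had an unadjusted p under 0.05, and the 2 groups did not overlap for 37.5% of the kept probe sets, where chance gives 20%. The count of called probe sets varied widely with the array left out, in fits that also have fewer residual degrees of freedom. It was 22 without ICD replicate 2, 151 without ICD replicate 3, 11 without HMM replicate 2 and 843 without ICD replicate 1. The count of higher probe sets was 1 without ICD replicate 2 or without HMM replicate 2, 30 without ICD replicate 3, 66 without HMM replicate 1 and 362 without ICD replicate 1, and that of lower probe sets was 21, 10 and 121 without ICD replicate 2, HMM replicate 2 and ICD replicate 3. All 504 differences kept their direction with any array left out. The 504 were selected with every array included, for differences that were large against their spread. Where the groups do not overlap, leaving out an array cannot reverse the direction. The kept direction is therefore no separate check of the calls.

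Ionocyte genes showed the deepest falls. The acid- and base-secreting cells of the larval skin depend on foxi1, their master transcription factor, and foxi1.L read 7.9 ± 8.67 in ICD (SD, n = 3) against 1843 ± 414 in HMM (SD, n = 2). The difference of -7.22 ± 0.49 (SE) on the log2 scale, 149-fold, had a limma adjusted p of 0.0032. The transcription factor gene ubp1.L fell by 6.14. The anion exchanger gene slc26a4l.L fell by 6.87, and the carbonic anhydrase genes ca12.L, ca2.S and ca2.L had differences of -6.04, -5.95 and -5.07. The monocarboxylate transporter gene slc16a3.L and the anion exchanger gene slc4a1.L differed by -4.31 and -3.52, both past the threshold. The probe sets of several of these genes were near the pseudocount in ICD, so their folds are understated. Of 19 measured members of the ionocyte list, 8 were lower, 1 was higher and 10 did not pass; adjusted over the list alone, 11 were lower and 2 higher. The higher member was foxi4.2.L, a fork head gene, at 369 ± 80.9 in ICD (SD, n = 3) and 83.1 ± 48.1 in HMM (SD, n = 2), with a difference of 2.16. It was not called without ICD replicate 2, ICD replicate 3 or HMM replicate 2, and its homeolog foxi4.2.S differed by 0.40 and did not pass. The median of the list was -1.24 and its mean -2.17 (camera adjusted p = 1.8e-08; adjusted p = 0.26 with an estimated correlation). The number of lower members was 5 without HMM replicate 2, and 6 to 8 without any 1 of the other arrays.

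Part of the genes of the vacuolar proton pump, which ionocytes use to secrete acid, fell as well. Of 18 measured V-ATPase genes, 9 were lower in ICD and 9 did not pass, and adjusted over the list alone 13 were lower. The largest differences were those of atp6v0a4.L (-6.00), atp6v0d2.L (-5.90) and atp6v1b1.L (-5.14). For atp6v0d2.L the signal was 39.5 ± 6.64 in ICD (SD, n = 3) and 2902 ± 1562 in HMM (SD, n = 2). The accessory subunit gene atp6ap1.1.L, which is not on the list, fell by 5.62. The subunit gene atp6v1e1.L fell by 2.44. The catalytic subunit gene atp6v1a.L differed by -0.75 and did not pass (limma adjusted p = 0.117), with the same outcome for its other probe set. Over the list the median was -1.31 (camera adjusted p = 6.1e-14; adjusted p = 0.28 with an estimated correlation). The number of lower members was 3 without ICD replicate 2, 6 without ICD replicate 3 and 1 without HMM replicate 2.

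Genes of motile cilia, the beating organelles of the multiciliated skin cells, were lower in ICD almost throughout. Of 40 measured components 30 fell, none rose and 10 did not pass; adjusted over the list alone, 38 were lower. The list's median difference was -2.86, or 7.24-fold (camera adjusted p = 6.1e-30; adjusted p = 0.28 with an estimated correlation). The tektin gene tekt2.S, which encodes a filament of the axoneme, read 47.6 ± 29.6 in ICD (SD, n = 3) and 725 ± 321 in HMM (SD, n = 2), a difference of -3.91. It was the largest of the list's called members, nearly tied with that of ak7.S (-3.90). Other called members were the central-pair gene spag6.L (-3.61), the dynein light chain gene dnal4.S (-2.70), the dynein assembly gene dnaaf4.L (-2.69), the outer dynein arm docking gene odad4.L (-2.32) and daw1.S (-2.33). Of the 8 called lower ionocyte genes, 6 lay below the lowest of these cilia genes. No member was called without ICD replicate 2 or without HMM replicate 2, where 1588 and 1091 of all probe sets had an unadjusted p under 0.05; 17 were called without ICD replicate 3 and 23 without HMM replicate 1. With each array left out, 38 or 39 of the 40 differences stayed below 0.

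Of 14 measured regulators of multiciliated cells, 6 were lower and 8 did not pass, and adjusted over the list alone 10 were lower. Called members were the transcription factor genes foxn4.S (-2.70) and rfx2.S (-1.91), the centriole amplification gene ccdc78.S (-3.95), the centriole duplication kinase gene plk4.L (-1.70) and the helicase gene ruvbl2.L (-1.71). For ccno.L, a cyclin of centriole amplification, the signal was 263 ± 209 in ICD (SD, n = 3) and 1601 ± 421 in HMM (SD, n = 2), a difference of -3.17 that did not pass (limma adjusted p = 0.128). ICD replicate 1 read 31.7 for it and ICD replicates 2 and 3 read 319.5 and 439, and without ICD replicate 1 the difference was -2.05 and was called (limma adjusted p = 0.00668). The geminin genes gmnn.L and gmnn.S, whose protein restrains DNA replication, differed by 2.00 and 1.63, in the other direction, and did not pass. Without ICD replicate 1, which read 943 and 851 where ICD replicates 2 and 3 read 124 to 185, they differed by 1.11 and 0.90. The regulators' median was -1.48 (camera adjusted p = 5.9e-06; adjusted p = 0.28 with an estimated correlation). The mRNAs of foxj1 and mcidas were not analysed here, and myb was too dim to keep. Of 16 intraflagellar transport and BBSome genes, which build and supply cilia, 7 were lower and 9 did not pass, and adjusted over the list alone 13 were lower. Examples were ift80.L (-2.37), ift57.S (-2.15), bbs5.L (-1.81) and the transition-zone gene b9d1.L (-1.53). Their median was -1.79 (camera adjusted p = 1.8e-10; adjusted p = 0.28 with an estimated correlation). Without ICD replicate 2 or HMM replicate 2 no member of either list was called. Without ICD replicate 3, 2 regulators and 1 transport gene were called, and 2 regulators were called without HMM replicate 1.

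**Figure D1:**
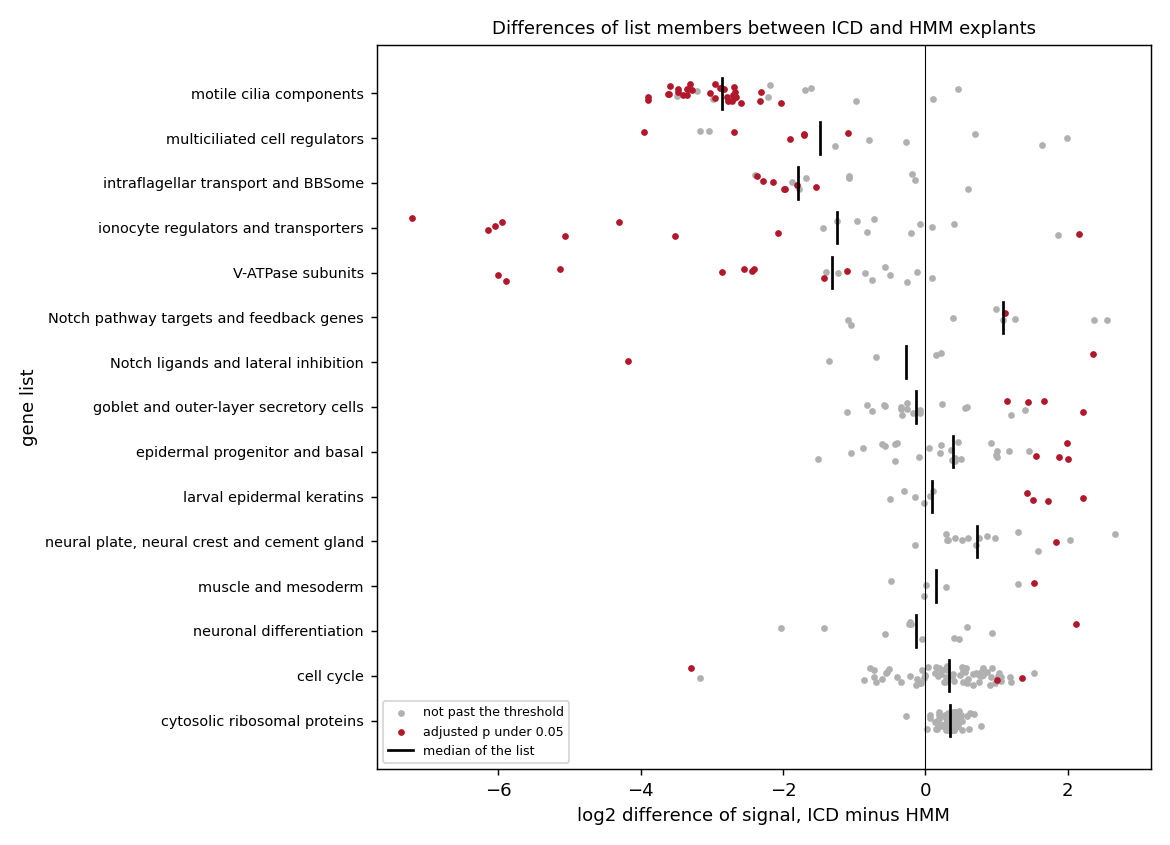
Differences of the measured members of each gene list on the log2 scale, ICD (3 arrays) minus HMM (2 arrays). Each point is a gene, red where its limma adjusted p was under 0.05, and the bar is the list's median. The motile cilia list centres on -2.86, and the ionocyte and V-ATPase lists reach -7.22 and -6.00.

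Of 9 measured genes on the list of Notch targets and feedback genes, notch1.S included, 7 had differences above 0 and 1 passed. This was hes4.L, a transcriptional repressor, which rose from 1045 ± 42.4 in HMM (SD, n = 2) to 2283 ± 225 in ICD (SD, n = 3), a difference of 1.12 (limma adjusted p = 0.0247; 0.0502 in eBayes without trend, where it was not called). The other 8 did not pass. Adjusted over the list alone, 4 were higher, 1 of them notch1.S, and 1 was lower. The repressor genes hey1.S and hes5.1.L differed by 2.37 and 2.55, with limma adjusted p of 0.14 and 0.322. ICD replicate 1 read 661 for hes5.1.L, where ICD replicates 2 and 3 read 44.7 and 23. The differences of hes5.10.L and hes4.S were 1.26 and 1.09, and those of hes1.L and hes1.S were -1.09 and -1.04. Without ICD replicate 1 the differences of hey1.S, hes5.1.L, hes5.10.L and hes4.S were 1.56, 1.17, 1.00 and 0.52, and hey1.S was then called (limma adjusted p = 0.0464). Without HMM replicate 2, which read 312.7 for hes1.S where HMM replicate 1 read 58.4, hes1.S differed by 0.114. The median was 1.09, and the list's camera adjusted p of 0.0527 did not pass (adjusted p = 0.28 with an estimated correlation), while fry gave an adjusted p of 0.0271. With notch1.S left out, a choice made after seeing the data, the median of the other 8 was 1.104 and the camera adjusted p 0.0997. For all 9, without ICD replicate 1, 2 or 3 that camera adjusted p was 0.0320, 0.0309 or 0.0301, without HMM replicate 2 it was 0.00701, and without HMM replicate 1 it was 0.268. No member of the list was called without ICD replicate 2 or 3 or without either HMM replicate. The remaining hes5 and hes7 genes and nrarp were too dim to keep.

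The ligand list moved both ways. The ligand gene jag1.L rose from 29.5 ± 15.8 in HMM (SD, n = 2) to 167 ± 24.9 in ICD (SD, n = 3), a difference of 2.35. The ubiquitin ligase gene neurl1.L, whose product acts on Notch ligands, fell by 4.18. The ligand genes dll1.L and dlc.L differed by -0.70 and -1.35 and did not pass. Over the 6 measured genes 1 was higher, 1 lower and 4 did not pass, with the same counts adjusted over the list alone. The median was -0.27 and the list did not pass (camera adjusted p = 0.552; adjusted p = 0.62 with an estimated correlation). With each array left out, that median ran from -0.60, without ICD replicate 2, to -0.0554, without ICD replicate 1, where dlc.L differed by -0.72 and dll1.L by 0.00763. Neither jag1.L nor neurl1.L was called without ICD replicate 2 or without HMM replicate 2, and jag1.L was not called without ICD replicate 3.

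**Figure D2:**
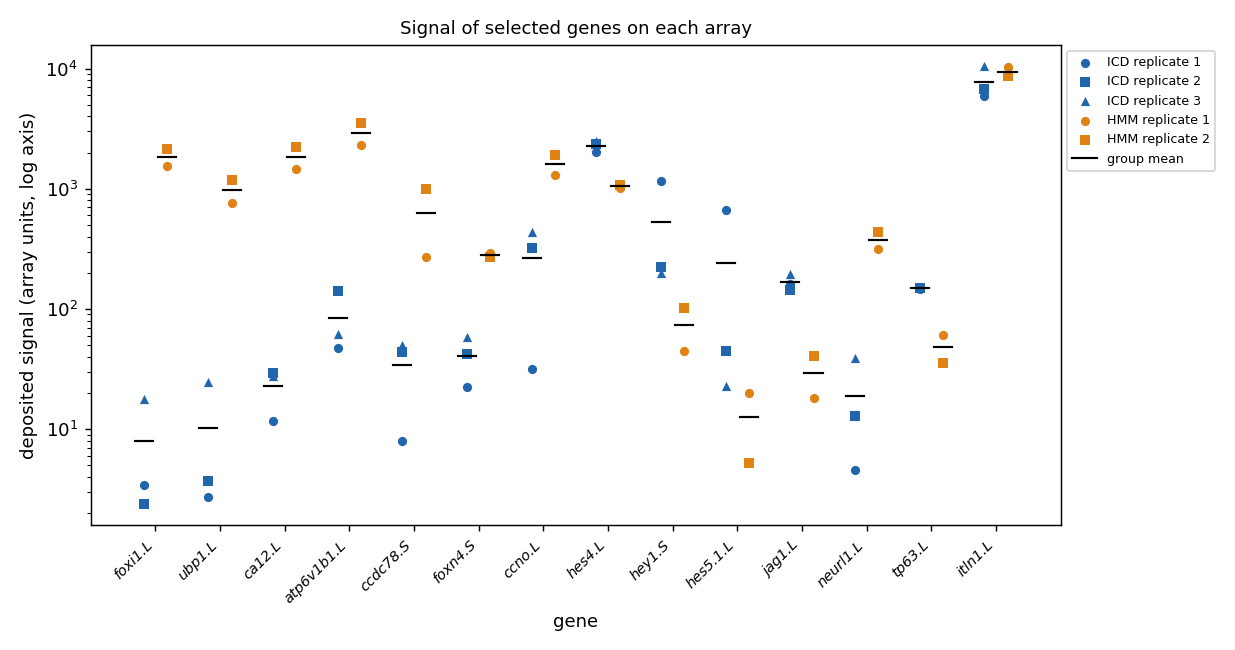
Deposited signal of selected genes on each array, on a log axis, with ICD arrays in blue, HMM arrays in orange, the marker shape giving the replicate and the line the group mean. The mean of foxi1.L was 7.9 in ICD and 1843 in HMM, while itln1.L read at least 5925 on every array and hes5.1.L was highest on ICD replicate 1.

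Genes of the outer layer and of the basal epidermis gave a mixed picture. Of 22 measured goblet and outer-layer genes 4 rose, none fell and 18 did not pass; adjusted over the list alone, 5 were higher. The protein disulfide isomerase genes agr2.S and ag1.S rose, with differences of 1.45 and 1.15, as did the tight junction gene cldn1.S (1.66) and the calpain gene capn8.3.L (2.21). RNA of whole explants does not show which cells expressed these genes. Whether other tissue, such as cement gland, was their source was not tested. The lectin gene itln1.L, a main product of goblet cells, read 7706 ± 2376 in ICD (SD, n = 3) and 9423 ± 1147 in HMM (SD, n = 2), and its difference of -0.33 did not pass (limma adjusted p = 0.524; from -0.57 to -0.16 with each array left out). For this list the median was -0.13 while the mean was 0.22 and the test's direction up, and the camera adjusted p was 0.712, where fry gave an adjusted p of 0.0418. Of 28 progenitor and basal genes 4 rose and 24 did not pass, with 8 higher adjusted over the list alone. They were the integrin gene itga3.L (2.00), klf17.L (2.00), zfp36l1.S (1.88) and tp63.L (1.56), a transcription factor of basal epidermis. Their list had a median of 0.39 (camera adjusted p = 0.0658), and the list passed without ICD replicate 3 (adjusted p = 0.0134) and without HMM replicate 1 (adjusted p = 0.0447). Its median was 0.25 without ICD replicate 2 (adjusted p = 0.124) and 0.21 without HMM replicate 2 (adjusted p = 0.134). Of 10 keratin genes, krt19.S, krt19.L, krt18.1.S and krt18.1.L rose, with differences of 2.22, 1.73, 1.51 and 1.43, and the other 6 differed by -0.49 to 0.11 and did not pass. The same 4 were higher adjusted over the list alone. The keratin median was 0.09 (camera adjusted p = 0.0782). That list passed without ICD replicate 1, ICD replicate 2 or HMM replicate 1 (adjusted p = 0.0320, 0.0271 and 0.0447), and its median was -0.0696 without ICD replicate 3. None of the members of these 3 lists was called higher without ICD replicate 2 or without HMM replicate 2. Without ICD replicate 3 or HMM replicate 1, 2 progenitor and 2 keratin genes were called. Of the 4 small secretory cell genes, too few for a test, pnhd.L rose by 2.60, a call that was lost without ICD replicate 2 or HMM replicate 2, while foxa1.S, slc18a1.S and htr3a.L differed by -0.29, -0.53 and -0.40 and did not pass. The serotonin synthesis gene tph1 was too dim to keep.

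Markers of tissues other than epidermis were measured as well. Of 16 genes of neural plate, neural crest and cement gland, 15 had differences above 0, with a median of 0.73 (camera adjusted p = 0.000861; adjusted p = 0.48 with an estimated correlation and 0.12 with fry). Without ICD replicate 1, whose mean level over the list was -0.24 where ICD replicates 2 and 3 lay at 0.66 and 0.71, the median was 1.13. The head transcription factor gene otx1.L rose by 1.84 and was the list's 1 called member, where 3 were higher adjusted over the list alone. It was not called without ICD replicate 2, ICD replicate 3 or HMM replicate 2, and 8 members were called without ICD replicate 1. The genes snai1.S, pitx1.L and snai2.S differed by 2.67, 2.03 and 1.31 and did not pass. Among 6 muscle and mesoderm genes, ckm.L, a creatine kinase gene, rose by 1.52, while its 2 other probe sets, at 1.32 and 1.29, did not pass. Its call was lost without ICD replicate 2, ICD replicate 3 or HMM replicate 2. The muscle median was 0.14 (camera adjusted p = 0.343). The skeletal alpha 1 actin control probe set read 39.1, 211.5 and 119.7 on the ICD arrays and 56.9 and 119.7 on the HMM arrays. Among 12 neuronal genes, prph.S, which encodes an intermediate filament, rose by 2.11, a call that was lost without any 1 array other than ICD replicate 1, and chga.L differed by -2.04 without passing. Adjusted over the list alone, 1 neuronal gene was higher and 1 lower, and the median was -0.13 (camera adjusted p = 0.653). The 2 measured endoderm genes, gata6.L and a2m.S, differed by -0.34 and -0.31 and did not pass.

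Few cell cycle genes passed. Of 74 measured genes, mcm5.L, part of the replication helicase, and ccnd1.S, a G1 cyclin, rose, with differences of 1.35 and 1.01. The cyclin gene ccna1.S read 62.5 ± 38.5 in ICD (SD, n = 3) and 619 ± 229 in HMM (SD, n = 2) and was 9.84-fold lower. None of these 3 calls held without ICD replicate 2 or without HMM replicate 2. The call of ccnd1.S was lost without any 1 of the 5 arrays, and that of mcm5.L also without ICD replicate 3 or HMM replicate 1. The other 71 did not pass, and adjusted over the list alone 2 were higher and 2 lower. The cell cycle median was 0.34 (camera adjusted p = 0.0196; adjusted p = 0.62 with an estimated correlation), and its call was lost without ICD replicate 1 (adjusted p = 0.104) and without HMM replicate 2 (adjusted p = 0.604). Its median was 0.0447 without HMM replicate 2 and 0.69 without HMM replicate 1, whose mean level over the list (0.0799) lay above that of ICD replicate 2 (0.00289), while HMM replicate 2 lay at -0.39. With fry the adjusted p was 0.274. The 70 ribosomal protein genes, included as a reference group, had a median of 0.35, with 69 above 0 and no call from limma. The camera adjusted p of this list was 6.5e-08 (adjusted p = 0.52 with an estimated correlation and 0.0867 with fry). The cell cycle median of 0.34 was thus no larger than that of the reference group, and a list shift of this size cannot be told apart from it.

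Outside the lists, the largest called rises among named genes were those of the microfibril gene fbn3.L (2.98), the somatostatin gene sst.1.L (2.98) and ambp.L (2.63), whose other 3 probe sets lay between -0.34 and 0.01 and did not pass. The secreted olfactomedin gene olfm4.L rose from 316 ± 22.1 in HMM (SD, n = 2) to 1821 ± 413 in ICD (SD, n = 3), a difference of 2.48. The others were the collagen gene col18a1.L (2.32), the matrix link protein gene hapln3.L (2.31), the collagen chaperone gene fkbp10.L (2.30), the iron reductase gene cybrd1.L (2.36) and the transcriptional repressor gene tgif2.S (2.51). The gene annotated as xfrp rose by 2.39. Among the falls outside the lists were those of fetub.S (-6.03) and smpx.L (-4.46). Of the 60 called genes named by the rule, 8 passed whichever array was left out. They were foxi1.L, slc26a4l.L, ca12.L, ca2.S, ca2.L, atp6v0d2.L, atp6ap1.1.L and slc16a3.L.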

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

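The 3 control probe sets below were picked by a rule set after the data had been seen, a highest ICD array above 1.5 times the highest HMM array, and they enter no comparison of the groups. The middle probe set for skeletal alpha 1 actin, a muscle gene, read 211.5 on ICD replicate 2, against 56.9 and 119.7 on the HMM arrays and 39.1 and 119.7 on the other ICD arrays. The middle probe set for beta actin read 8162 on ICD replicate 3, 5186 and 5540 on the other ICD arrays, and 3706 and 3866 on the HMM arrays. The middle probe set for the hybridization control BioB read 294.3 on ICD replicate 3 and 102.7 to 147.5 on the other 4 arrays. That array also lacked poly-A control signal, with a median of 2.95. Of the 151 probe sets called without ICD replicate 3, all 151 had the left-out array on the same side of the HMM mean as the other ICD arrays.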

How the results depend on the processing

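Including homeolog pairs and counting list members with arrays left out were chosen after seeing the data. The count of 504 called probe sets stayed within 1.5 times under both scalings, both pseudocounts, both filters and both variance settings. Of the 60 called genes named by the rule, 54 kept their call under all of those. The gene dnaaf4.L kept it in all but the stricter filter, where it was not fitted. The genes smpx.L, ccnd1.S, krt18.1.L, prph.S and hes4.L lost it under at least 1, and prph.S was not fitted under the stricter filter either. Called genes that the text names outside the rule do not enter this count. An adjusted p under 0.1 gave 857, 299 higher and 558 lower. The median difference of all probe sets was 0.08, and 0.11 after median centring. With each array left out, the count of probe sets past the threshold ranged from 11 to 843, the probe sets higher in ICD from 1 to 362 and those lower in ICD from 10 to 481. Fewer samples enter those fits, and with 1 HMM array left its spread was taken to be that of ICD. With an estimated correlation no list passed. The medians of the motile cilia, regulator, intraflagellar transport, ionocyte and V-ATPase lists stayed at -2.86, -1.48, -1.79, -1.24 and -1.31 without a call. With fry these 5 lists passed (adjusted p = 0.0418, 0.0271, 0.0418, 0.0163 and 0.0271), as did the goblet list (adjusted p = 0.0418). The neural, ribosomal and cell cycle lists lost their call in both tests. The loss with an estimated correlation is not due to correlation alone, as that test has 3 degrees of freedom. The Notch target list had an estimated correlation of -0.0891, below the preset 0.01, and its camera adjusted p still went from 0.0527 to 0.279. The Notch target list passed with no pseudocount (median 1.11), no filter (0.93), the stricter filter and fry (1.09 in both), and with any ICD array or HMM replicate 2 left out, but not without HMM replicate 1 (medians from 0.93, without HMM replicate 1, to 1.16 over the 5 arrays). Its adjusted p was 0.0527 in the main setting and ran from 0.00701 to 0.279 over the alternatives; the cause was not tested.

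Replicate numbers 1 and 2 occur in both groups, but the labels do not say that they pair samples. Deviations from the group means correlated at 0.65 for number 1 and 0.51 for number 2, with ICD replicate 3 at 0.40 with HMM replicate 2. The deviations of the 2 HMM arrays are equal and opposite, and those of the ICD arrays cancel out. These values are therefore not separate pieces of evidence for pairing. With the replicate block the count was 1714, with 744 probe sets higher in ICD and 970 lower, and included all 504. ICD replicate 3 has no partner, so it adds nothing to the difference in this fit, which has 1 residual degree of freedom. Its differences equal those without ICD replicate 3, where 151 probe sets were called with no block. The sign changes of gata6.L (0.18) and of the keratin (-0.0696), muscle (-0.0132) and neuronal (0.0755) medians therefore come from losing that array.

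The Notch ligand median turned to 0.16 with the stricter filter, where fewer genes were tested, and the muscle median to -0.0856 with no filter. With each array left out, values that had not passed changed sign for dll1.L (-1.19 to 0.00763), htr3a.L (-1.67 to 0.875), gata6.L (-0.78 to 0.18), a2m.S (-0.72 to 0.0897), tnni2.S (-1.11 to 0.13), pax3.L (-0.23 to 0.80), foxa1.S (-1.02 to 0.44), foxi4.2.S (-0.40 to 1.19) and hes1.S (-2.19 to 0.114). The medians of goblet (-0.24 to 0.000575), keratin (-0.0696 to 0.22), muscle (-0.0132 to 0.45) and neuronal (-0.16 to 0.26) genes did so as well. The cause was not tested for any of these.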

Other observations

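A group of extracellular matrix and matrix receptor genes was picked after its values were seen. Of 15 measured collagen, integrin and matrix metalloproteinase genes, 2 of which (itga3.L and itga6.L) are also on the basal epidermis list, 6 were higher in ICD and none was lower. They were col18a1.L and col18a1.S, 2 homeologs of a basement membrane collagen gene, the metalloproteinase genes mmp3.L and mmp28.L, and the integrin genes itga3.L and itgb1.S. For mmp3.L the signal was 822 ± 115 in ICD (SD, n = 3) and 172 ± 67.0 in HMM (SD, n = 2), a difference of 2.26. The family's median was 1.23 (camera p = 4.8e-07; p = 0.107 with an estimated correlation), and as the family was picked for its values, neither p counts as evidence for it. None of the 6 calls held without ICD replicate 2 or without HMM replicate 2, and 3 held without ICD replicate 3. The largest called rise of all was on a probe set with no gene symbol, which read 1638, 694 and 372 on the ICD arrays and 21.3 and 17.5 on the HMM arrays. Of the 21 replication genes of the cell cycle list, 19 had differences above 0 (median 0.75, 1 called), and of its 35 mitosis genes 20 did (median 0.20, none called by limma); this split was also made after the values were seen.

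In the next 2 patterns the tests were chosen after the result was seen, except for the test of early-stage genes, whose threshold was written before their values. That test was prompted by a few early genes seen among the differences between arrays, which the list leaves out. Some probe sets split arrays 1 and 2 of both groups by replicate number. The tetraspanin gene tspan8.L read 2070, 1.8 and 1216 on ICD replicates 1, 2 and 3, and 2573 and 1.7 on HMM replicates 1 and 2. The oxygen-sensing gene egln3.L read 114, 1422 and 1209, and 304 and 1322. ICD replicate 3 lay nearer the number 1 arrays for tspan8.L and nearer the number 2 arrays for egln3.L, and over the 15 probe sets at least 4-fold apart between the numbers it did so for 3 and 12. After quantile normalization 13 probe sets were this far apart, against 15 without it. The arrays already shared a trimmed mean close to 200.03, so this count could hardly fall and does little to test array scaling. The 13 were counted anew over all kept probe sets and were not matched to the 15. With the HMM arrays the other way round, 0 probe sets were as far apart. With ICD replicate 3 in the place of ICD replicate 2, 17 were, and again 0 with the HMM arrays the other way round. The split is therefore not particular to the arrays numbered 2. Younger explants in replicate 1 are a further candidate explanation for part of it. Over 20 measured genes of oocyte, blastula and gastrula stages, among them pou5f3.1.L and zar1.S, the median difference between the numbers was 0.40. This lay above 99.8% of 10000 random lists matched on signal. Those lists were drawn gene by gene, so they lack movement shared by related genes, and homeologs such as those of wee1 counted apart. Cell cycle genes, some of them among the 20, also lay higher on replicate 1 than on replicate 2. Their mean level was 0.20 and 0.00289 in ICD, and 0.0799 and -0.39 in HMM. The 99.8% may therefore overstate the case for younger explants. As younger explants would give, 36 of 40 motile cilia genes were lowest on ICD replicate 1 within ICD, and 36 were lower on HMM replicate 1 than on HMM replicate 2. Clutch, day, handling and age stay open, since the labels record none of them per sample. RNA quality and labelling stay open as well. The ratio of 3' to 5' signal of the GAPDH control was 3.80 on ICD replicate 2 and 3.99 on HMM replicate 2. It was 2.75 on ICD replicate 1, 2.80 on ICD replicate 3 and 2.75 on HMM replicate 1. The same ratio for beta actin, 0.181 to 0.245 over the arrays, did not split the numbers.

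Some feedback genes of the Notch pathway were highest on ICD replicate 1. Of 11 hes5, hes7, hey1 and nrarp genes, dim ones included, 10 were highest there within ICD, with a median excess of 1.44 over the mean of the other 2 ICD arrays. For hey1.S the ICD arrays read 1155, 223 and 201. These genes were picked for the pattern. On the Notch target list of 9 genes, 4 were highest on that array within ICD and 5 lowest, namely hes4.L, hes1.L, hes1.S, notch1.S and rbpj.S. A difference shared by the number 1 arrays stays open: the 11 genes differed by a median of 0.10 between HMM replicates 1 and 2, but only 2 of them, hey1.S (-1.10) and hes5.10.L (-0.66), lay above the filter value on both HMM arrays. A stronger overall response in ICD replicate 1 stays undecided: over the 193 other genes called higher without that array, it lay a median of -0.67 from the other ICD arrays, with an SD of 0.91 over genes, and those genes were selected on the other arrays, which pulls the value down. On the 5 lists of cilia and ionocyte genes that were lower in ICD, ICD replicate 1 had the lowest mean level within ICD (for motile cilia -1.89, against -0.90 and -0.49; for V-ATPase -0.94, against -0.67 and -0.75), as a stronger response would give. HMM replicate 1 also lay below HMM replicate 2 on all 5 (for motile cilia 1.23 and 2.04), as a difference shared by the number 1 arrays or younger explants would give, so these levels do not separate the explanations. More injected RNA in that sample is a possible explanation that these data do not test, since the dose per sample is not given in the sources used here.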
